A study of Homo sapiens with 3 samples.

How the data were processed

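H3K27ac and H3K4me3 were measured by chromatin immunoprecipitation and sequencing in HCC1599 cells, with 1 library per mark and an input library without antibody. Per the labels' protocols, chromatin was cross-linked with formaldehyde in live cells and fragmented by sonication and micrococcal nuclease, and libraries were made with a KAPA Hyper Prep kit; per the labels, the antibodies came from Active Motif for H3K27ac and from Cell Signaling Technology for H3K4me3. The submitters' processing notes name Bowtie2, whose version is not given in the sources used here, MACS 1.4 and the build hg38, with no parameters. The authors deposited 1 peak list per mark, each with the position of every peak and a score. The deposited score has no stated unit. Its minimum of 30 and its pile-up at 3100 are like the scaled negative logarithm of the p-value that MACS 1.4 writes, with a numerical limit, but the sources used here do not say so, and it is used only to describe, rank and filter peaks within a list. The score does not rank the 33.4% of H3K4me3 peaks that share the value 3100; 0.546% scored higher, up to 3233. Micrococcal nuclease cuts between nucleosomes and the marks are nucleosomal, so that edges and gaps of peaks depend on the digestion and on how the caller joined neighbouring peaks. Signal tracks and the input were not analysed here, and neither read depth nor local copy number could be read from the peak lists.

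Peaks on chromosomes 1 to 22 and X were used, and positions are given counted from 1 in hg38. Gene positions came from a RefSeq table of GRCh38.p14, which is the same build family, with 19974 protein-coding genes and 59098 genes of any kind on these chromosomes. The table gives the span and kind of each gene but no strand, transcripts, exons or sequence. The plan had placed promoters at the start of 1 selected transcript per gene, so the planned definition was replaced: a mark was called at a gene where a peak overlapped, by at least 1 bp, the 1 kb either side of either annotated end of the gene. This counts far ends as well as starts, and it misses starts inside a span. Exon and intron annotation, the alternative with every transcript start, matching of random lists on CpG content and the planned search for sequence motifs were not run for the same reason. A peak was distal if it lay more than 2.5 kb from the ends of genes of every kind. Peaks elsewhere were assigned by their midpoint. Distal H3K27ac peaks less than 12.5 kb apart were joined into clusters and ranked by the length their peaks covered.

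The marks were compared by overlap of at least 1 bp. The value beside each overlap is the mean over 1000 random placements of peaks within their chromosomes, whose ends were taken from the last gene or peak, and 100 placements were used for the marks of genes; placements ignore gaps in the assembly and sequence that reads cannot be placed in, so that the folds are not corrected for these. For each of 24 gene lists, with 364 different genes, all of which were found in the gene table, the share of members with both marks and the mean number of distal H3K27ac peaks within 50 kb of either end were set against 10000 random lists of protein-coding genes of the same size. The percentile counts ties by their midpoint. Confidence intervals for shares are exact Clopper-Pearson intervals at 95%. Peaks near one another and genes that share a peak are not independent, so these intervals are too narrow as errors of the experiment, and with 1 library per mark the difference between repeat libraries is unknown.

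The genes named were fixed by a rule set before the data were examined: MARCO; in each list, up to 6 members of the smaller states in list order and the first 4 of the largest state; the genes at the 15 widest H3K4me3 peaks at protein-coding gene ends; and the gene nearest to each of the 15 largest distal H3K27ac clusters. Some genes and regions that this rule takes are not reported here. KRT19, named for sharing a peak with KRT15, LOC124906072, in the MARCO span, AXL, ANKRD37, the H3K27ac ranking by width and the genes of peak-free stretches were chosen after their values were seen. Alternatives set before the data were examined were a score of at least 100, equal list lengths, 50% of a peak covered, a circular shift in place of free placement, windows of 500 bp and 2.5 kb, a distal distance of 5 kb, ends of protein-coding genes only, flanks of 100 kb, merging of peaks less than 500 bp apart, a joining distance of 5 kb and ranking by summed score. A score of at least 50, any peak in the gene span or within 1 kb of it, and random lists matched on gene density were added after seeing the data. The plan had assumed a score minimum of 50, and the files start at 30. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and bedtools 2.31.1. The overlap counts were checked against bedtools and differed by 0, and in tests on simulated data with the 19974 genes 4.25% of lists drawn at random lay above the 95th percentile.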

Results

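Chromatin of HCC1599, an established triple-negative breast cancer cell line, was profiled by chromatin immunoprecipitation and sequencing with an antibody to H3K27ac, the acetylated histone mark found at active promoters and enhancers, and with an antibody to H3K4me3, the trimethylated mark found at promoters. The series held 3 samples, one for each mark and an input without antibody, and each mark was represented by 1 library. No value below therefore has a replicate check, and no p-value is given; intervals are exact Clopper-Pearson 95% binomial intervals over peaks or genes, which cover counting error only and treat neighbouring peaks as independent. The H3K27ac list held 72895 peaks and the H3K4me3 list 32045, of which 72894 and 32043 lay on chromosomes 1 to 22 and X and were used. The number of reads behind each list is unknown here, so a site without a peak is a site where none was called, not a site shown to lack the mark.

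H3K27ac peaks were more numerous and narrower than H3K4me3 peaks. Their median width was 865 bp (interquartile range 559 to 1743) against 1667 bp (892.5 to 3060.5) for H3K4me3, and they covered 106 Mb and 71.0 Mb respectively. The widest H3K27ac peak spanned 58355 bp over EN1, a homeobox transcription factor gene, and the widest H3K4me3 peak spanned 38262 bp over ZNF217, a zinc finger gene. The score the authors gave each peak ran from 30 in both lists, with a median of 65.0 for H3K27ac and 590 for H3K4me3, and 2701 H3K27ac peaks (3.71%) and 10875 H3K4me3 peaks (33.9%) scored 3100 or above, most of them exactly 3100, with a maximum of 3233 in both lists. Scores below 100 made up 60.1% of the H3K27ac list and 30.1% of the H3K4me3 list.

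The series was designed to find where H3K27ac and H3K4me3 lie in cells carrying a transcript of MARCO that its labels call MARCO-TST. MARCO, which encodes a class A scavenger receptor of macrophages, held 9 H3K27ac peaks and no H3K4me3 peak. The gene spans positions 118942194 to 118994660 of chromosome 2 (hg38), 52467 bp, of which the H3K27ac peaks covered 14796 bp. They lay toward the higher-coordinate end of the gene, the first beginning 22852 bp from the lower-coordinate end. Its lower-coordinate end carried neither mark and its higher-coordinate end carried H3K27ac alone. The gene table used here gave no strand; from general knowledge MARCO is read toward higher coordinates, which makes the unmarked end its annotated start.

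The strongest MARCO peak, at 118986769 to 118990844, was 4076 bp wide with a score of 1661 and overlapped LOC124906072, a gene annotated within the MARCO span. The next strongest, at 118981930 to 118983789, scored 734. Peaks at 118970342 to 118972337, 118972364 to 118974968 and 118980805 to 118981844 scored 317.5, 177 and 257, and the peak at 118992503 to 118994011, at the higher-coordinate end, scored 154. The other 3 had scores of 45.6, 41.5 and 57.1. Within 50 kb of MARCO there was 1 further H3K27ac peak, at 118901400 to 118902822 with a score of 61.0, and there was no H3K4me3 peak. Among 6421 protein-coding genes of 0.5 to 2 times its length, MARCO stood at percentile 96.8 for the number of H3K27ac peaks in the gene, a comparison chosen after its values were seen.

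EN1, at 118842171 to 118847648 and 94545 bp from MARCO, was its marked neighbour. It lay inside the widest H3K27ac peak of the list, at 118799615 to 118857969, and inside the second widest H3K4me3 peak at a protein-coding gene, at 118820835 to 118856717 and 35883 bp wide. Both peaks had a score of 3100. A second H3K27ac peak of 7076 bp, at 118858047 to 118865122, followed after a gap of under 100 bp and also had a score of 3100. H3K4me3 came no closer to MARCO than a peak of 663 bp at 118882735 to 118883397, 58797 bp from the gene.

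**Figure D1:**
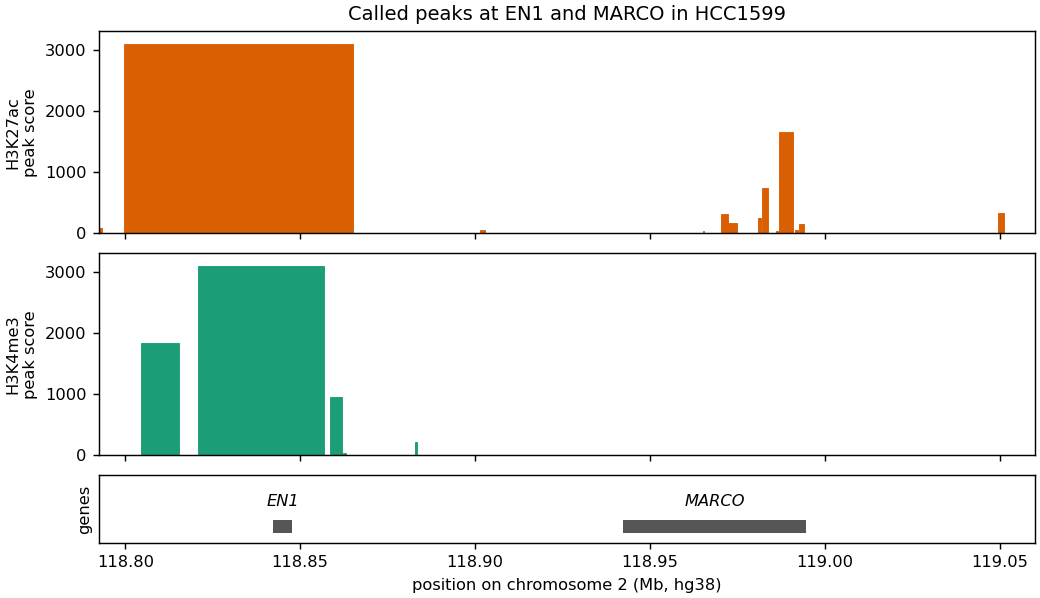
Called H3K27ac peaks (upper panel) and H3K4me3 peaks (middle panel) over EN1 and MARCO on chromosome 2, with position in Mb on the horizontal axis and the authors' peak score on the vertical axis; each bar spans 1 peak and the lower panel shows the annotated genes. H3K27ac has 9 peaks within MARCO, where H3K4me3 has none, and both marks reach 3100 over EN1.

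The next comparison asked how far the marks share sites. H3K4me3 peaks lay on H3K27ac peaks in most cases: 22752 of 32043 (71.0%, 70.5 to 71.5) overlapped one by at least 1 bp, 7.67-fold more than the mean of 9.25% over 1000 random placements of the H3K27ac peaks (8.77 to 9.78%). Of the 72894 H3K27ac peaks, 25335 (34.8%, 34.4 to 35.1) overlapped H3K4me3, 8.48-fold over the placements' 4.10%. The folds depend on the overlap required: with 50% of a peak covered, the shares were 57.6% (18.6-fold) for H3K4me3 and 28.4% (11.3-fold) for H3K27ac. Shared peaks were the wider and stronger ones. H3K27ac peaks that overlapped H3K4me3 had a median width of 1687 bp and a median score of 363, against 648 bp and 46.5 for the others, and 47.9% against 3.93% of them lay at the end of a protein-coding gene. H3K4me3 peaks that overlapped H3K27ac had a median width of 2214 bp and a median score of 1778, against 994 bp and 141.

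The share of H3K27ac peaks on H3K4me3 rose with the H3K27ac score, from 10.2% of peaks scoring 30 to 50 to 94.7% of those at 3100 or above. Peaks more than 2.5 kb from every gene end rose in the same way, from 4.93% to 89.8%. Transcript starts inside a gene's span were not known here, so these peaks can include peaks at promoters there. The 34.8% is therefore a value for this list at its own threshold, and it was 53.9% among peaks scoring at least 100 in both lists.

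**Figure D2:**
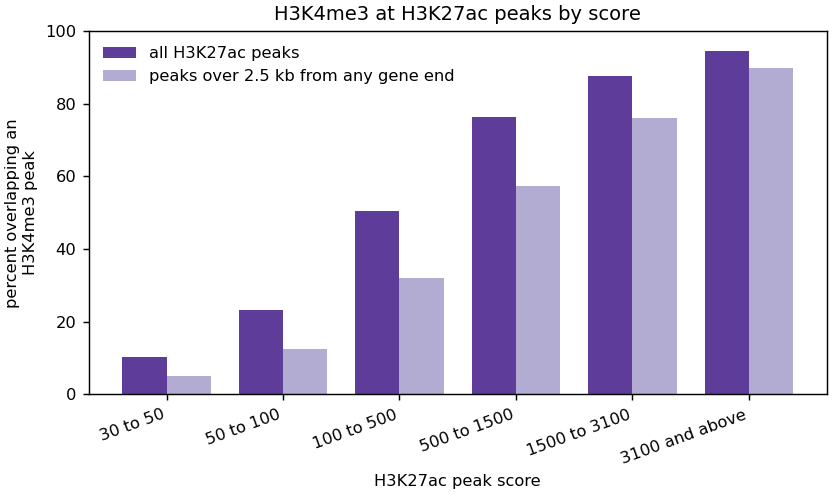
Percent of H3K27ac peaks that overlap an H3K4me3 peak (vertical axis), by the H3K27ac peak score (horizontal axis), for all H3K27ac peaks (dark bars) and for those more than 2.5 kb from any annotated gene end (light bars). The dark bars run from 10.2% to 94.7% and the light bars from 4.93% to 89.8%. The light bars can include peaks at transcript starts inside a gene's span.

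H3K4me3 peaks lay at gene ends more often than H3K27ac peaks. H3K4me3 had 13546 of its peaks (42.3%, 41.7 to 42.8) within 1 kb of an annotated end of a protein-coding gene, 7.61-fold over random placement, and H3K27ac had 13999 (19.2%, 18.9 to 19.5), 4.33-fold over random placement. The gene table used here gave no strand, so the start and the far end of a gene were both counted as ends. Peaks centred inside protein-coding genes but away from their ends made up 45.7% of H3K27ac and 31.8% of H3K4me3, and peaks outside any gene 25.1% and 17.5%. H3K27ac peaks more than 2.5 kb from the ends of genes of every kind, called distal here, numbered 47559 (65.2%, 64.9 to 65.6). Of these, 8762 (18.4%, 18.1 to 18.8) overlapped H3K4me3, against 65.4% of the H3K27ac peaks closer to gene ends. H3K4me3 had 13344 distal peaks, of which 66.9% overlapped H3K27ac. Distal peaks of either mark can lie at transcript starts inside a gene's span. With scores of at least 100, the shares at gene ends were 57.2% for H3K4me3 and 35.5% for H3K27ac, and with equal list lengths they were 42.3% and 33.6%.

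Of 19974 protein-coding genes, 11501 (57.6%, 56.9 to 58.3) had both marks within 1 kb of an end, 2382 (11.9%) had H3K4me3 only, 631 (3.16%) had H3K27ac only, as MARCO did, and 5460 (27.3%) had neither. Random placement of both lists gave 1.83% with both marks. H3K4me3 was mostly at 1 end, in 11817 genes, and at both ends in 2066; where it was at 1 end, H3K27ac was at that same end in 80.0% of the genes and at the other end in 10.8%. Genes with both marks had wider H3K4me3 (median 3752 bp) than genes with H3K4me3 alone (1869.5 bp). Across the 11501 genes, which are not independent replicates, the widths of the marks rose together (Spearman's rho 0.61). Where H3K27ac was alone its peaks were weak, with a median score of 70.2 against 696 in genes with both marks, and the number of such genes was 353 with scores of at least 100. This count leaves out peaks inside a gene's span, whether at starts there or elsewhere: with any peak in the span or within 1 kb of it, 1464 genes had H3K4me3 only and 1032 had H3K27ac only.

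Gene lists fixed before the data were examined differed widely in their marks, from 100% of housekeeping, ribosomal protein and cell cycle genes with both to none of the olfactory receptor genes. Against 10000 random lists of the same size, 9 of the 24 lists lay above the 95th percentile for the share of members with both marks and 7 below the 5th, where chance would put about 1 list each. These percentiles describe these libraries and are not tests. A gene with neither mark had none at its ends: of the 80 list members in this state, 13 had H3K4me3 and 19 had H3K27ac elsewhere in the gene or within 1 kb of it. Single marks are likewise those at the ends: of 43 members with H3K4me3 only, 18 had H3K27ac elsewhere in the gene, and of 15 with H3K27ac only, 2 had H3K4me3. A mark at the end of a gene can belong to a neighbour, as at KRT15 and KRT19, which shared 1 peak of each mark. For distal H3K27ac within 50 kb, 7 lists lay above the 95th percentile. Besides luminal progenitor, epithelial junction and hypoxia genes, these were basal genes (mean 4.84 peaks, percentile 98.99), chromatin regulators (4.55, 98.1), luminal genes (4.75, 97.9) and breast cancer drivers (4.56, 97.3), against random medians near 2.9. Olfactory receptor, HOX, other developmental and lymphocyte genes lay below the 5th. Among peaks scoring at least 100, drivers left the upper group (93.8) and cell cycle genes entered it (96.5). Within 100 kb, luminal (92.1) and hypoxia genes (94.3) left it and housekeeping (97.1) and Notch genes (96.7) entered, while lymphocyte genes left the lower group (17.9) and macrophage genes entered it (1.24). A longer gene has more sequence within 50 kb of its ends. The random lists were not matched on gene length, so the percentiles for distal H3K27ac can partly reflect it.

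All 15 housekeeping genes, all 15 ribosomal protein genes and all 15 cell cycle genes carried both marks, each list at percentile 99.99. ACTB and GAPDH had H3K4me3 peaks of 7544 and 6490 bp, and PGK1 and TBP peaks of 6657 and 6678 bp. Ribosomal RPL3, RPL5, RPL7 and RPL11 had H3K4me3 peaks of 7417, 6844, 13141 and 6691 bp. MKI67, the proliferation marker, had 5967 bp of H3K4me3 and 2902 bp of H3K27ac, TOP2A, a DNA topoisomerase gene, 3364 and 1543 bp, and the cyclin genes CCNB1 and CCNB2 4633 and 3513 bp of H3K4me3. Of 16 DNA repair genes, 15 had both marks (percentile 99.89), BRCA1, BRCA2 and PALB2 of homologous recombination among them, and TP53BP1 had H3K4me3 only. BRCA1 and BRCA2 had H3K27ac scores of 1146 and 1377, and PALB2 263.

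Chromatin regulators had both marks at 18 of 20 genes (percentile 99.9), including the acetyltransferase genes EP300, CREBBP and KAT2A and the methyltransferase gene KMT2A. KAT2B had H3K4me3 only, and SETD1B had neither mark at its ends but 3 H3K4me3 and 4 H3K27ac peaks in its span. Breast cancer driver genes had both marks at 17 of 18 (percentile 99.97). MYC lay in 11045 bp of H3K4me3 and 22805 bp of H3K27ac, CCND1, encoding cyclin D1, in 10237 and 8133 bp, and EGFR had 4422 and 3773 bp. ERBB2, encoding HER2, had an H3K27ac score of 319, below the 3100 of MYC and CCND1 and the 2715 of EGFR. MET, a receptor tyrosine kinase gene, had an H3K4me3 score of 3100 and no H3K27ac at its ends.

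Basal and luminal epithelial genes differed in their counts, though that difference was not tested. Of 19 basal genes, 15 had both marks (78.9%, 54.4 to 93.9, percentile 97.2). KRT5, the basal keratin, had 7963 bp of H3K4me3 and 7578 bp of H3K27ac, KRT15 10697 and 11903 bp and KRT16 1677 and 4354 bp. KRT14 had only a weak H3K27ac peak, with a score of 47.3, KRT17 only a weak H3K4me3 peak, with a score of 58.3, and KRT6B neither. TP63, the p63 transcription factor gene, had neither mark at its ends but 3 H3K4me3 and 6 H3K27ac peaks in its span. Of 16 luminal genes, 6 had both marks (37.5%, 15.2 to 64.6, percentile 5.85) and 5 had H3K4me3 only (percentile 97.9). The progesterone receptor gene PGR was among the latter, with an H3K4me3 score of 1627, as were AGR2, MLPH and CA12. SPDEF had H3K27ac only. TFF1 and TFF3, which are estrogen-responsive trefoil factor genes, had neither mark. ESR1, the estrogen receptor gene, and GATA3 had neither at their ends, but ESR1 had 5 H3K4me3 and 18 H3K27ac peaks in its span and GATA3 had 3 and 4. FOXA1 had both, with an H3K27ac score of 44.8. XBP1 had an H3K27ac score of 3100, as did KRT8, and KRT18 had 2362.

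Luminal progenitor genes had both marks at 6 of 8 (percentile 82.6) and the highest distal H3K27ac count of the 24 lists. A mean of 9.88 distal H3K27ac peaks (SD 5.79 over the 8 genes) lay within 50 kb of their ends, against a random median of 2.88 (percentile 99.99). PROM1, encoding CD133, had 18, the receptor tyrosine kinase gene KIT 17, ELF5, a transcription factor of the luminal progenitor, 12, and ALDH1A3 12. These counts include distal peaks inside the genes. In the span or within 1 kb of it, PROM1 held 16 H3K27ac peaks, KIT 10, ELF5 8 and ALDH1A3 7, not all of them necessarily distal. PROM1 had 13912 bp of H3K4me3 and ALDH1A3 8466 bp. SOX10 and LTF had neither mark at their ends, with 8 and 5 distal peaks within 50 kb of them. LTF held 2 H3K27ac peaks, which can be among its 5. Epithelial junction and identity genes had both marks at 17 of 18 (percentile 99.94) and a mean of 5.33 distal peaks (percentile 99.6). E-cadherin gene CDH1 had 12 and the claudin genes CLDN3 and CLDN4 had 13 each, whose flanks overlap one another. EPCAM had 7024 bp of H3K4me3 and 4 distal peaks. TJP1 had H3K4me3 only at its ends and 8 H3K27ac peaks in its span.

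Mesenchymal transition genes had both marks at 6 of 12 (percentile 29.9), with a median H3K27ac score of 156 over the 6 and the highest, 1497, at AXL, a receptor tyrosine kinase gene. ZEB1 and SNAI2, repressors of epithelial genes, had H3K4me3 scores of 3100 with H3K27ac scores of 174 and 34.7, TWIST1 had 139 and SNAI1 451. VIM, encoding vimentin, CDH2, encoding N-cadherin, and FN1, encoding fibronectin, had H3K4me3 only, TWIST2 H3K27ac only, and ZEB2 and SPARC neither, although ZEB2 had 2 H3K4me3 peaks in its span, and VIM and FN1 had 1 H3K27ac peak each.

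Genes of other cell types mostly lacked both marks at their ends, in 33 of 53 fibroblast, macrophage, lymphocyte and endothelial genes, of which 10 had a peak elsewhere in the gene. Of 11 fibroblast genes 1 had both marks (ACTA2, percentile 0.06), and COL1A2, COL3A1, DCN and PDGFRB were among 6 with neither at their ends, with 1 H3K27ac peak inside COL1A2 and PDGFRB each and 1 H3K4me3 peak inside COL3A1; COL1A1 and PDGFRA had H3K4me3 only and LUM and FAP H3K27ac only. Of 15 macrophage genes 3 had both (CD68, FCGR3A and SPI1, percentile 0.175), with CD163, CSF1R, MRC1 and ITGAM, which held 3 H3K27ac peaks in its span, among 10 with neither at their ends, CD14 with H3K4me3 only and TYROBP with H3K27ac only. The H3K27ac score at SPI1, a myeloid transcription factor gene, was 40. Of 15 lymphocyte genes 1 had both (percentile 0), which was CD8A with an H3K27ac score of 58.7. The T cell receptor complex genes CD3D, CD3E and CD3G and CD2 were among 10 with neither at their ends. CD4 and CD79A had H3K4me3 only, and CD79B and GZMB had H3K27ac only. Of 12 endothelial genes 2 had both (ENG and ESAM, percentile 0.21), PECAM1, VWF, CDH5 and TEK were among 7 with neither at their ends, and KDR, CLDN5 and ERG had H3K4me3 only. VWF held 7 H3K27ac peaks in its span, PECAM1 3 and TEK 1. Lymphocyte genes also had few distal H3K27ac peaks, a mean of 1.53 (percentile 2.15).

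Scavenger receptor genes, the family of MARCO, had both marks at 5 of 13 (percentile 9.27), and at 3 of 13 with scores of at least 100 (percentile 3.04). SCARB1, a receptor for high-density lipoprotein, had a score of 3100 for both marks and 12 distal H3K27ac peaks, SCARB2 had an H3K27ac score of 431, and SCARA3 and SCARA5 had H3K27ac scores of 30.4 and 43.7. MARCO, with 7 distal peaks, and STAB1 had H3K27ac only, COLEC12 had H3K4me3 only, and MSR1, CD36, OLR1 and STAB2 had neither at their ends. STAB2 held 2 H3K4me3 and 7 H3K27ac peaks in its span, COLEC12 held 6 H3K27ac peaks and STAB1 held 1 H3K4me3 peak.

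Hypoxia and glycolysis genes had both marks at 21 of 23 (percentile 99.98) and a mean of 4.83 distal peaks (percentile 99.5). HIF1A and EPAS1, the hypoxia-inducible factor genes, ARNT, their partner, and VHL were among them, with H3K27ac scores of 2728.5, 311, 519 and 1283. EGLN3, a HIF prolyl hydroxylase gene, had H3K4me3 only, and PFKFB4 had neither at its ends but 2 H3K4me3 and 5 H3K27ac peaks in its span. Notch pathway genes had both marks at 14 of 19 (percentile 92.0). NOTCH1 had 24214 bp of H3K27ac and 12380 bp of H3K4me3, NOTCH3 5320 and 6129 bp, and NOTCH2 and NOTCH4 had both marks too. The ligand genes DLL1, DLL3 and DLL4 and the target gene HEYL had H3K4me3 only, and RBPJ, the DNA-binding partner of Notch, had neither at its ends but 4 H3K4me3 and 17 H3K27ac peaks in its span.

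Interferon response genes had both marks at 12 of 17 (percentile 85.7), with H3K27ac scores of 1241 at IRF1, 108 at IRF7, and 130 at IRF9. IFIT1, IFI44L and BST2 had H3K4me3 only, and OAS2 and IFI27 had neither at their ends. Antigen presentation genes had both marks at 11 of 14 (percentile 94.2). The class I genes HLA-B, HLA-C and HLA-E had both, and the 3 genes with neither at their ends were the class II genes HLA-DRA and HLA-DPA1 and the invariant chain gene CD74.

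Developmental regulators outside the HOX clusters often had H3K4me3 without H3K27ac at their ends. Of 16, 6 were in this state (percentile 99.6, and 96.9 among random lists matched on gene density, where HOX genes stood at 97.7 and luminal genes at 97.2), including NKX2-5 and PAX2, PAX6 and PAX7, which held 1, 1 and 3 H3K27ac peaks elsewhere in their spans, and 5 had both marks (percentile 1.92): NKX2-1, OLIG1, LHX2, HAND2 and WT1, with a median H3K27ac score of 59.9. PAX3 had H3K27ac only, and GATA4, TBX5 and NEUROD1 were among 4 with neither at their ends. HOX genes had both marks at 6 of 12 (percentile 30.5), among them HOXA5, HOXA13 and HOXC6; HOXB2, HOXB7 and HOXD3 had H3K4me3 only, HOXA9 H3K27ac only, and HOXB13 and HOXD10 neither. Distal H3K27ac was sparse around both lists, with means of 1.5 (percentile 1.48) and 1.08 (percentile 0.405). Among peaks scoring at least 100 these percentiles were 12.4 and 17.6, and with random lists matched on gene density the share of developmental regulators with both marks stood at percentile 8.49.

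Genes of other differentiated tissues had both marks at 2 of 16 (percentile 0.01), MBP and GRIN1. ALB, APOA2, TTR and FGB, which encode plasma proteins of the liver, were among 8 with neither, APOA1, ACTN2, SYP and SNAP25 had H3K4me3 only, and TNNT2 and GFAP had H3K27ac only. Of 13 olfactory receptor genes none had both marks, which allows a share of up to 24.7%. OR1A1, OR1A2, OR4D1 and OR5A1 were among 12 with neither, and OR2C1 had an H3K27ac peak with a score of 32.7, near the minimum of the list.

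**Figure D3:**
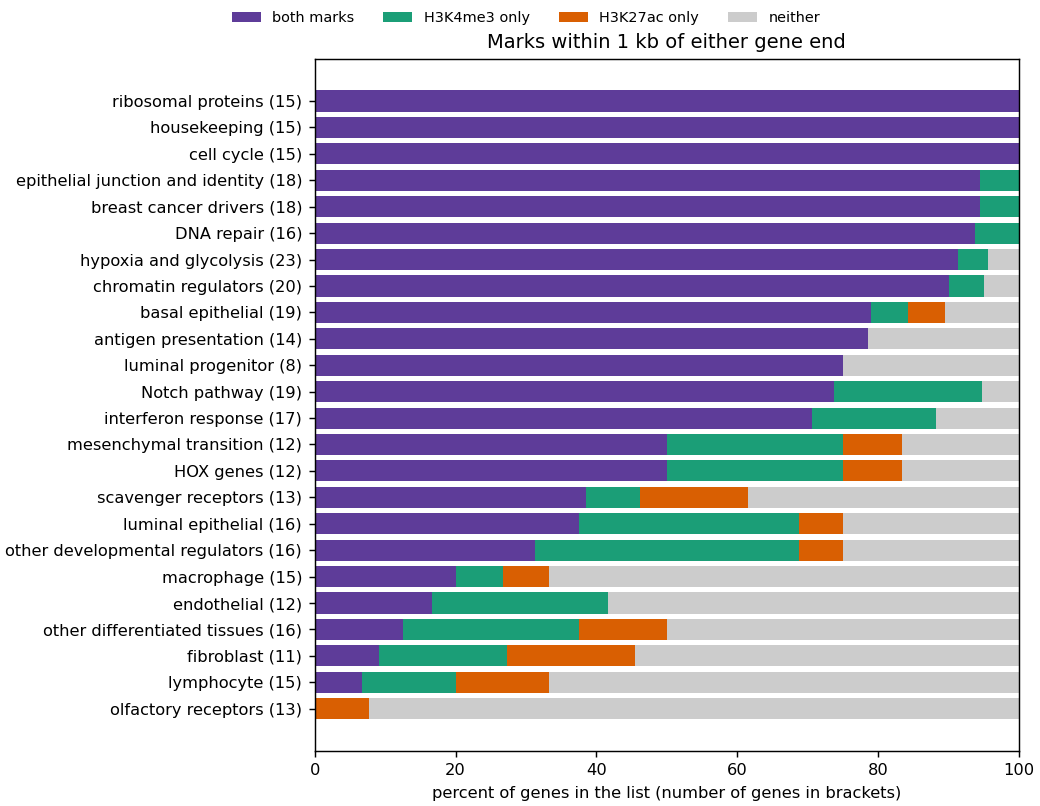
Percent of the genes of each fixed list (horizontal axis, number of genes in brackets) with both marks, H3K4me3 only, H3K27ac only or neither within 1 kb of either gene end. Housekeeping, ribosomal protein and cell cycle genes stand at 100% with both marks, and olfactory receptor genes at 0%.

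The 15 widest H3K4me3 peaks at protein-coding gene ends had scores of 3100. After ZNF217 and EN1 came the peak of MCL1, an anti-apoptotic gene, and ADAMTSL4 (27892 bp), then TRPS1, a GATA-type transcription factor gene (27715 bp), ESYT2 (27439 bp), EHF, an epithelial ETS factor gene (24221 bp), CYP1B1 with RMDN2 (22674 bp) and TM4SF1 (22654 bp). ACTN4 (20630 bp), BARX2 (18900 bp), EFNA1 with DPM3 and SLC50A1 (18566 bp), GCNT2 (18179 bp), ANXA2 (18134 bp), HOXC10 with HOXC9 (17795 bp) and FOXC1, a forkhead factor gene of basal-like breast cancer (17777 bp), followed. With peaks less than 500 bp apart merged, 11 of the 15 regions stayed among the widest and NFIX came first at 42240 bp.

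Neighbouring distal H3K27ac peaks were joined into 28080 clusters, of which 18752 held a single peak and 164 held 10 or more. Among the 15 with the most covered sequence were clusters in MYH9, encoding non-muscle myosin heavy chain (62310 bp), and in ARHGEF10L (60465 bp). Those nearest RNF113B (58080 bp, within FARP1), CTBP2 (57920 bp), BCAS1 (54463 bp, 103358 bp away), MAML2, a Notch coactivator gene (52294 bp), FANCC (51987 bp, within AOPEP) and SIPA1L3 (51844 bp) came after. Further clusters were nearest to IGF1R, encoding a growth factor receptor (50852 bp), NFIX (50447 bp), B4GALT5 (47810 bp), RHPN2 (47179 bp) and WWTR1, encoding the coactivator TAZ (46691 bp). The nearest gene is a statement of distance only. This ranking depended on its settings, with 8 of the 15 regions shared at a joining distance of 5 kb and 7 when clusters were ranked by summed score.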

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

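The H3K27ac list held 1 peak outside the chromosomes used, on the mitochondrial chromosome at positions 5994 to 7421, 1428 bp wide with a score of 89.91. It stood out as a signal in data that the comparisons did not use, since mitochondrial DNA carries no nucleosomes. The H3K4me3 list held no peak there. No explanation for it was tested.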

How the results depend on the processing

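There were 80 alternatives to the results that answer a comparison. Of these, 45 stayed within the main value's interval or within 1.5 times its count, and 35 moved. Some of the 45 could not move. Examples are score filters on the 0 H3K4me3 peaks of MARCO and H3K4me3 at gene ends with equal list lengths, which leave that list whole. Another is a score filter on the 15 widest H3K4me3 peaks at gene ends, which all scored 3100. Only the size of each value was labelled, and a reversal of direction was not looked for. The cause of a move was not tested except where the setting itself sets it. With scores of at least 100, the share of H3K4me3 on H3K27ac was 66.3% (11.4-fold) and that of H3K27ac on H3K4me3 53.9% (12.2-fold), the shares at gene ends were 35.5% for H3K27ac and 57.2% for H3K4me3, 48.5% of H3K27ac was distal, 353 genes had H3K27ac only, MARCO and its flanks held 6 H3K27ac peaks, and 2 lists were low for distal H3K27ac. With equal list lengths, which leave the H3K4me3 list whole, the overlaps were 61.8% (11.4-fold) for H3K4me3 and 62.0% (12.0-fold) for H3K27ac. The full lists gave 71.0% and 34.8%. Shares over lists of equal length are close wherever peaks overlap mostly 1 to 1, so the loss of the larger share for H3K4me3 follows largely from this setting. With equal list lengths H3K27ac at gene ends was 33.6% and 283 genes had H3K27ac only. A score of at least 50, added after seeing the data, gave 9.90-fold for H3K4me3, and 46.7% and 10.9-fold for H3K27ac. With 50% of a peak covered, the shares were 57.6% (18.6-fold) and 28.4% (11.3-fold), and a circular shift gave 8.39-fold for H3K4me3. Windows of 500 bp and 2.5 kb put 17.4% and 24.0% of H3K27ac and 40.6% and 46.8% of H3K4me3 at gene ends. Distal H3K27ac was 55.1% at 5 kb and 76.0% with ends of protein-coding genes only. Counting the whole gene span, added after seeing the data, left 1464 genes with H3K4me3 only and 1032 with H3K27ac only. Within 100 kb of MARCO there were 4 H3K4me3 peaks, all toward EN1. Of the 15 largest clusters, 8 were shared at a joining distance of 5 kb and 7 when ranked by summed score. The same 9 lists lay above the 95th percentile for both marks with scores of at least 100, with windows of 2.5 kb and with random lists matched on gene density, and of the 7 below the 5th the other developmental regulators left in the last of these. Of 48 alternatives for single lists 47 stayed within intervals that are wide for 8 to 23 genes, and lymphocyte genes went to 0%. Within them, developmental regulators with both marks went from 5 to 2 of 16 with scores of at least 100. Endothelial genes went from 2 to 1 of 12 at that setting. With windows of 2.5 kb, genes of other differentiated tissues went from 2 to 5 of 16 and fibroblast genes from 1 to 2 of 11. Transcript starts, CpG matching and motifs were not run. Read depth is unknown, so that weak sites of either mark cannot be called absent.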

Other observations

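The tests in this part concern patterns that were seen in the results. For the sequence flanking EN1 the bound was set before its value was computed. The other tests were chosen after the results were seen. Several stretches with 11 or more protein-coding genes had no peak of either mark. One on chromosome 4, from 185661149 to 190196239 (4.54 Mb), held 13 protein-coding genes, among them FAT1, an atypical cadherin gene, TLR3, the receptor for double-stranded RNA, CYP4V2, and the clotting genes F11 and KLKB1. ANKRD37, a hypoxia-induced gene at 185396841 to 185400723 on the same chromosome, had both marks, with 7445 bp of H3K4me3. Others were on chromosome 11, where the beta-globin genes HBB, HBD, HBE1, HBG1 and HBG2 and 29 olfactory receptor genes lay in 0.94 Mb without a peak and 15 genes of the MS4A family, MS4A1 among them, in 0.747 Mb. SMN1 and SMN2, near-identical copies, lay in a stretch of 1.41 Mb on chromosome 5 with 11 protein-coding genes. Some stretches began at position 1 of a chromosome. They were 2.80 Mb of X with 16 protein-coding genes, 17.0 Mb of chromosome 15 with 15 and 10.7 Mb of chromosome 22 with 12. Whether reads could be placed in peak-free stretches, whether these cells keep the DNA there, and whether gene positions there are right, was not checked. Such stretches are not shown to lack the marks, and the genes counted with neither mark include genes in them.

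Ranked by width, which was not planned, the H3K27ac list had EN1, NFIX (43367 bp), ZNF217 (41467 bp), TM4SF1 (35977 bp) and RHOV with SPINT1 (33832 bp) at its head, and NOTCH1 stood at rank 13 with 24214 bp. Absence of H3K27ac at gene ends went with the H3K4me3 score: 6.03% of the 10650 genes scoring 3100 or above lacked it, against 40.9% of 1409 genes scoring 1500 to 3100, 62.1% of 914 scoring 500 to 1500, 69.9% of 617 scoring 100 to 500 and 56.3% of 293 below 100.

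EN1 lay in the widest H3K27ac peak of the list, and if raised copy number or background in the region were the cause, the peaks from 100 kb to 1 Mb either side were predicted to cover more than in 95% of such windows around genes; they covered 6.27%, against a median of 5.29%, at percentile 58.0 of 19974 windows. Among the 1000 windows nearest in number of protein-coding genes, a comparison chosen after that value was seen, the percentile was 78.4. The predicted rise in the covered share of these flanks was thus not found. Copy number itself was not measured, and whether a gain or raised background lengthens called peaks was not checked. Either therefore stays open, in the flanks as within 100 kb. Low input coverage shared by both lists cannot be told apart from marks that truly lie together: 12 of the 20 widest H3K27ac peaks overlapped one of the 20 widest H3K4me3 peaks, and the input itself was not analysed here. With a single cell line and no comparison group, no biological explanation was tested.

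MARCO held 9 H3K27ac peaks and no H3K4me3 peak. Of 973 protein-coding genes of similar length without H3K4me3 in the gene it alone held 9 or more. That set was chosen by the lack of H3K4me3 seen at MARCO, so this rank is not a test. Among all 6421 genes of similar length MARCO stood at percentile 96.8 for the number of peaks and 94.9 for the covered share. Calls scattered by chance along the chromosome did not reach 9 peaks: over 1000 random placements the highest count in MARCO was 6. Placements spread peaks evenly, whereas called peaks gathered at gene ends, so the count of 6 does not set MARCO apart from other genes. False calls among the 9 and local background that gathers them stay open, as the input was not analysed here. Each peak was then set against H3K27ac peaks of like score and width, up to 25% higher or lower by the same factor, that lay likewise more than 2.5 kb from every gene end (6 peaks) or closer (3 peaks). Like peaks usually lacked H3K4me3 for 5 of the distal ones, where 2.55%, 37.3%, 24.2%, 42.0% and 5.63% overlapped it, but not for the distal peak scoring 734 (59.5%), the strongest peak (89.5%, 384 of 429) or the one at the higher-coordinate end (61.8%), and the peak scoring 57.1 was undecided (49.9%). The closer class pools gene starts with far ends, as the gene table gave no strand. Its shares can thus be those of peaks at starts, and they do not show that the 3 closer MARCO peaks are unusual for a far end. The strongest peak ended at 118990844, more than 2.5 kb from the higher-coordinate end of MARCO at 118994660. It was therefore in the closer class through an end of another gene, which can be a start or a far end. All 3 closer peaks overlapped LOC124906072. A regulatory link to a MARCO transcript or to EN1 is a hypothesis these lists do not test, and no biological explanation was tested.

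H3K4me3 without H3K27ac was found at the ends of 2382 genes. H3K27ac can lie elsewhere in such genes, as it did in 18 of 43 list members in this state. With any peak in the span or within 1 kb of it, 1464 genes had H3K4me3 only. Not all of the 2382 genes had weak H3K4me3 near the detection limit. An H3K4me3 score of 3100 or above was found at 26.95% of them (25.2 to 28.8), against 87.0% of genes with both marks. The 1740 below it had a median score of 915 (95% interval 837 to 1012), far above the minimum of 30. Bounds for both values were chosen after the results were seen, so the values describe these genes and give no verdict on a cause. These genes nevertheless scored lower than genes with both marks, so that H3K27ac too weak to be called at weaker promoters remains open. Other developmental regulators stood at percentile 99.6 for this state, and at 96.9 among random lists matched on gene density, and other marks that could tell a poised promoter from a weak one were not analysed here; no biological explanation was tested.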
